A study of Caenorhabditis elegans with 12 samples.

How the data were processed

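Polyadenylated RNA of C. elegans was sequenced in 12 libraries, 3 cultures each of the genotypes labelled wt and glh1, with a total RNA and a polysomal RNA library from each lysate. Per the labels, larvae grew for about 40 h at 20 °C until most were young adults, polysomes were separated on 10 to 50% sucrose gradients, and reads of 75 cycles came from a stranded kit. Whether counting used the strand is not given in the sources used here. The tissue label reads whole embryo, which the growth protocol does not describe.

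The deposited count table holds estimated counts for 46904 gene IDs, and 3.79 to 4.80% of its values per library are not whole numbers to within 0.000001. The deposited table of rlog values, on a log2 scale, holds 12709 genes, those with a mean estimated count above 60. The authors list Trimmomatic 0.36, STAR 2.6.1b, RSEM 1.3.0, R 3.6.1 and DESeq2 1.24.0 with the genome WBcel235, while the name of the deposited count table points to kallisto, so the tool that made the counts is not known. Symbols, positions and exon lengths came from Ensembl release 115. A symbol was found for 44017 IDs and none for 2887, of which 87 were not in the annotation. Of the genes tested, 102 had counts identical to those of another gene in each library, and 51 symbols stood for more than 1 gene.

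Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 16526, libraries were scaled with TMM, and 1 quasi-likelihood model with robust dispersions was fitted to the 4 groups of 3 libraries. The 5 contrasts were glh1 against wt in total and in polysomal RNA, polysomal against total RNA in wt and in glh1, and their interaction. P-values were adjusted by the Benjamini and Hochberg method within each contrast, and genes under 0.05 were called. Log2 CPM values, as in the principal components and centred values, used a prior count of 2. Log2 fold changes are those of the fitted model, and levels are TMM-scaled CPM, counts scaled to a common library size. Library totals were 34520267 to 49672537 estimated counts, and the median SE of a log2 fold change was 0.306 in total RNA. Between replicates, chi-square per degree of freedom was 5.39 to 310, far above counting noise.

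In total, 31 gene lists were fixed before the data were examined, and so were the contrasts, the thresholds, the naming rule and the first set of alternatives. They cover major sperm proteins, other sperm genes, FLP and NLP neuropeptides, insulin-like peptides, peptide processing, pan-neuronal, muscle, intestine and male genes, vitellogenins, germline, oocyte, zygotic, P granule, small RNA and chromatin genes, collagens, molting, ribosomal proteins, translation factors, histones, mitochondrially encoded and respiratory chain genes, heat shock and unfolded protein response, antimicrobial effectors, C-type lectins, pals genes, cytochrome P450 and conjugation enzymes, and long noncoding RNAs. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Members were also adjusted over their list alone.

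Genes named in the text are the glh family, then called genes with an absolute log2 fold change of at least 1, at least 1 CPM in the higher group, groups that do not overlap and a gene-class name, ranked by fold change. Up to 12 per direction were named for the genotype contrasts, 8 for the fraction contrasts and 5 for the interaction, with up to 4 members of each list by smallest adjusted p. Gene functions given in the text are textbook knowledge.

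Total and polysomal libraries of a number came from 1 lysate, so the fraction contrasts are paired by design. Deviations from the group mean correlated within wt cultures (0.756, 0.440 and 0.304) and not within glh1 cultures (0.0990, -0.163 and -0.206), and the model without a block was kept as planned. Alternatives were DESeq2 size factors, upper-quartile scaling, no filter and a strict filter (5 CPM in 3 libraries), only the groups compared, a culture or number block, DESeq2 1.42.0, limma on the rlog values, a 2-fold minimum and each library left out. Chosen after the data were seen were leaving out wt culture 1 or polysomal glh1 library 3, removing annotated rRNA genes, and removing a trend on exon length from each library as an offset, alone or with the culture block, and testing lists with an estimated correlation without wt culture 1, without polysomal glh1 library 3 or with the offset. The test was checked on simulated data for total RNA, where 19 of 100 genes with a 2-fold change and 87 of 100 with a 4-fold change were called, with 6 false calls. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.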

Results

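The abundance of polyadenylated RNA was measured by sequencing in 12 libraries of the nematode Caenorhabditis elegans. The libraries came from 2 genotypes, labelled wt and glh1, with 3 cultures of each. GLH-1 is a Vasa-family helicase of P granules, the RNA granules of germ cells, and the series asks how gene expression and polysome loading differ with and without glh-1. Each lysate was divided into a part for total RNA and a part for polysomal RNA, the RNA in the polysome fraction of a sucrose gradient, so that each of 4 groups held 3 libraries. The tissue label reads whole embryo, whereas the growth protocol describes larvae grown for about 40 h at 20 °C until most were young adults. Library totals ran from 34520267 to 49672537 estimated counts, and 16526 genes were tested.

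The fractions separated on the first principal component, which held 54.7% of the variance. On the second component, which held 18.6%, wt cultures 2 and 3 lay between 37.8 and 64.2 in both fractions. Wt culture 1 lay at -28.7 in total RNA and -22.6 in polysomal RNA, inside the range of -31.5 to -18.4 of the libraries labelled glh1. The polysomal glh1 library 3 stood apart on the first component, at -136. Genes annotated as ribosomal RNA took from 3.07% of the counts in polysomal glh1 library 1 to 45.7% in polysomal glh1 library 2.

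**Figure D1:**
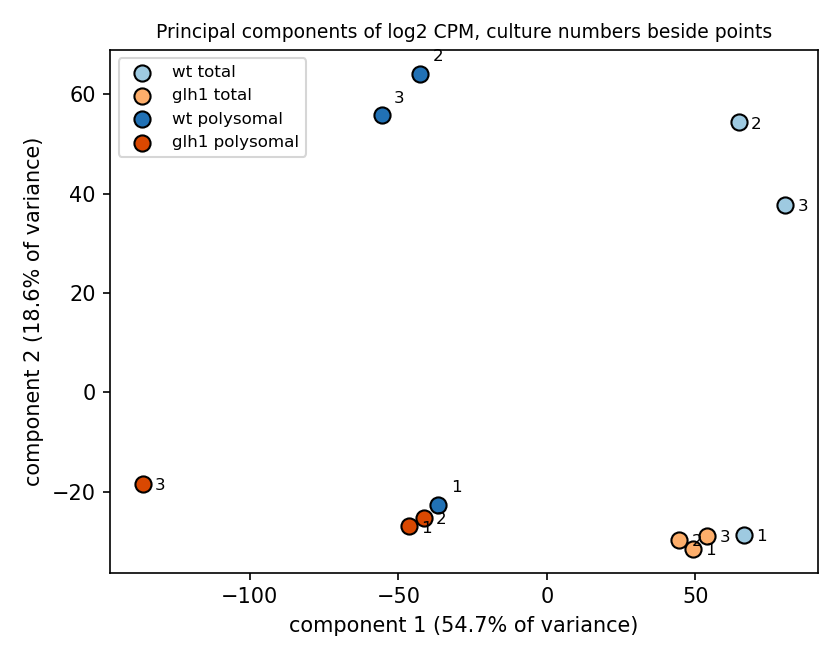
First and second principal components of log2 CPM for the 12 libraries, with the culture number beside each point. Wt culture 1 lies near the libraries labelled glh1 on the second component in both fractions, at -28.7 and -22.6.

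The targeted gene was more abundant, not less, in the libraries labelled glh1. In polysomal RNA, glh-1 (WBGene00001598, WBcel235 chromosome I, 6854478 to 6857536) rose from 355 ± 53.7 to 1094 ± 348 CPM (SD, n = 3), a log2 fold change of 1.62 ± 0.26 (SE; adjusted p = 0.0116). In total RNA it measured 345 ± 68.5 in wt and 554 ± 27.7 in glh1, a log2 fold change of 0.68 ± 0.26 that did not pass the test (adjusted p = 0.200). The polysomal call was lost without polysomal wt library 2 (adjusted p = 0.0684) or polysomal wt library 3 (adjusted p = 0.0577). It was also lost when only the polysomal libraries entered the fit (adjusted p = 0.307), whereas with only the total RNA libraries the difference in total RNA passed (adjusted p = 0.0191). The near-identical paralog glh-2 had log2 fold changes of 0.61 (adjusted p = 0.244) in total RNA and 0.83 (adjusted p = 0.150) in polysomal RNA, and how reads shared by glh-1 and glh-2 were divided is not known. The paralog glh-3 had 0.03 (adjusted p = 0.952) and 0.02 (adjusted p = 0.973), and glh-4 had -0.12 (adjusted p = 0.804) and 0.09 (adjusted p = 0.879). The allele is not given in the sources used here, and mRNA does not measure the protein, so glh1 is used below as a label only.

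**Figure D2:**
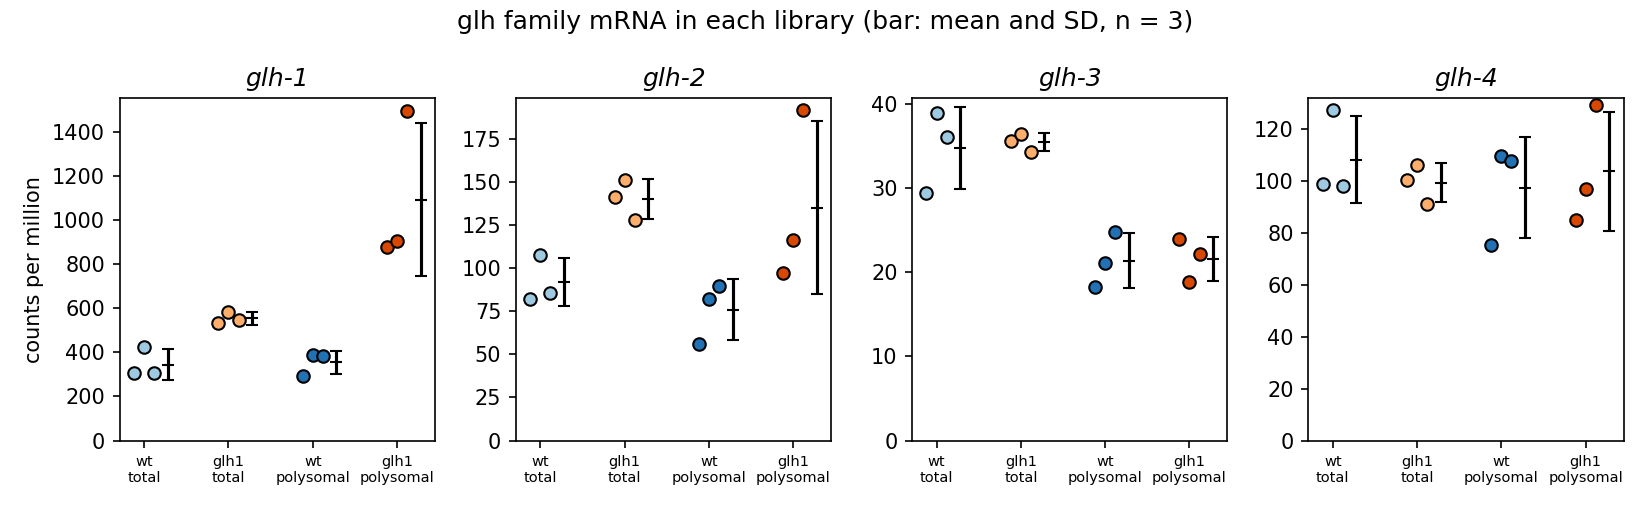
Normalised CPM of the 4 glh genes in each library (points), with the mean and SD of 3 libraries per group (bars). Each library labelled glh1 has more glh-1 mRNA than each wt library of the same fraction.

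The first comparison asks how steady-state mRNA differed between genotypes. In total RNA of the libraries labelled glh1, thn-1, which encodes a thaumatin-family protein, rose from 33.04 ± 3.71 to 185 ± 6.17 CPM (SD, n = 3), a log2 fold change of 2.48 ± 0.32 (SE; adjusted p = 0.00302). The genes clx-1 (3.59 ± 0.41, adjusted p = 0.00136), scl-5 (1.77 ± 0.24, adjusted p = 0.00361) and the ferritin gene ftn-1 (1.22 ± 0.16, adjusted p = 0.00361) rose as well. The zinc finger gene ztf-28 (-2.97 ± 0.23, adjusted p = 9.65e-05), the F-box gene fbxa-206 (-3.18 ± 0.34, adjusted p = 7.76e-04), the BATH-domain gene bath-7 (-2.44 ± 0.28, adjusted p = 0.00136) and the C-type lectin gene clec-223 (-1.90 ± 0.24, adjusted p = 0.00272) fell. These 8 genes kept an adjusted p under 0.05 when any of the 6 total RNA libraries was left out. Of those that fell, fbxa-206, bath-7 and clec-223 lay within 50 kb of other genes lower in glh1. Leaving out libraries cannot part strain background from genotype for any of them. The other genes with the largest rises under the naming rule were fipr-24 (3.39), tag-293 (2.96), col-50 (2.27), pqn-84 (1.88), clec-197 (1.82), vmo-1 (1.81), ecps-2 (1.67), ant-1.3 (1.66) and oac-31 (1.60). The other large falls under the naming rule were those of plk-3 (-2.43), bath-1 (-2.43), clec-227 (-2.18), the collagen gene col-80 (-2.16), bath-19 (-1.95), citk-1 (-1.88), scrm-4 (-1.65) and fbxb-66 (-1.63). Each gene of these last 2 groups lost its call without at least 1 library. Y102A5C.2, which has no class name, fell further (-5.44, adjusted p = 1.25e-05, the smallest of this comparison), with 1 count in its lowest glh1 library.

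Neuropeptide lists had higher medians in total RNA of the libraries labelled glh1 at the preset correlation, and few of their genes were called. The FLP precursors had a median log2 fold change of 0.55, with 0 of 30 called over all genes and 7 higher when adjusted over the list alone (adjusted p = 5.87e-11, and adjusted p = 0.679 with an estimated correlation). The NLP and PDF precursors had a median of 0.57 (adjusted p = 8.45e-13, and adjusted p = 0.679 with an estimated correlation). Of 73 measured, 3 rose, nlp-47 (0.93 ± 0.16), nlp-57 (1.43 ± 0.30) and nlp-69 (0.88 ± 0.19), and 6 were higher adjusted over the list alone. All 3 lost their calls without total glh1 library 2 (adjusted p = 0.121, 0.190 and 0.250). The insulin-like peptides had a median of 0.58, with 0 of 35 called and 0 adjusted over the list alone (adjusted p = 2.42e-05, and adjusted p = 0.848 with an estimated correlation). The peptide processing genes had a median of 0.28, with 0 of 18 called and 2 higher adjusted over the list alone (adjusted p = 0.00794, and adjusted p = 0.848 with an estimated correlation). The neuropeptide, insulin-like and sperm lists follow gene groups that the study reported on from these samples, so their direction is not independent evidence.

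Embryo, oocyte and germline lists had lower medians in total RNA of the libraries labelled glh1 at the preset correlation, and few of their genes were called. The zygotic embryo genes had a median of -0.78, with 0 of 38 called and 14 lower adjusted over the list alone (adjusted p = 3.92e-07, and adjusted p = 0.600 with an estimated correlation). The oocyte and maternal genes had a median of -0.48 (adjusted p = 6.01e-08, and adjusted p = 0.848 with an estimated correlation). Of 53 measured, 1 fell, the translational regulator lin-41 (-1.27 ± 0.21, adjusted p = 0.0124), and 3 were lower adjusted over the list alone. The germline proliferation and meiosis genes had a median of -0.32 (adjusted p = 1.15e-04, and adjusted p = 0.877 with an estimated correlation), and 1 of 53, the poly(A) polymerase gene gld-2, fell (-0.89 ± 0.17, adjusted p = 0.0274), 1 also adjusted over the list alone. The small RNA pathway had a median of -0.28, with 0 of 77 called, and 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.00125, and adjusted p = 0.856 with an estimated correlation). With the length trend removed its median was -0.17 and the call was lost (adjusted p = 0.0840). With upper-quartile scaling its median was -0.12 and the call was kept (adjusted p = 0.00761). Its median was -0.18 without total glh1 library 1, -0.17 without total wt library 2 and -0.14 without total wt library 3. The major sperm protein genes had a median of -0.65, with 0 of 30 called and 0 adjusted over the list alone (adjusted p = 3.34e-04, and adjusted p = 0.907 with an estimated correlation). Of the other 64 sperm genes smz-1 (1.23 ± 0.21) and smz-2 (1.22 ± 0.19) rose, and the list itself did not pass (adjusted p = 0.155). The calls of lin-41, gld-2, smz-1 and smz-2 were lost without total wt library 3 (adjusted p = 0.111, 0.203, 0.117 and 0.0852). The germline median was -0.51 without total wt library 1, -0.17 without library 2 and -0.19 without library 3. In total RNA, wt culture 1 lay below all 3 glh1 cultures for the germline (-0.26 against -0.21 to -0.09, centred log2) and chromatin lists (-0.26 against -0.18 to -0.05), so that those differences came from wt cultures 2 and 3. The zygotic, oocyte and vitellogenin lists were lower in wt culture 1 than in the other wt cultures too, and without that culture their medians were -0.92, -0.54 and -1.55. These 3 lists then passed with an estimated correlation too (adjusted p = 0.00834, 0.0378 and 0.00834). The test was chosen after the data were seen and takes out the lowest wt values of these lists, so the passes are no independent support.

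Another 7 lists passed the test in total RNA, and 6 of these calls were lost without at least 1 library. The antimicrobial effectors had a median of 0.18, with 2 of 95 higher, and 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.00332, and adjusted p = 0.877 with an estimated correlation). That call was lost without both libraries of wt culture 1 (adjusted p = 0.486), and the median was 0.31 without total wt library 1. The 6 vitellogenins, yolk proteins, had a median of -1.23 with 0 called and 2 lower adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.856 with an estimated correlation), lost without total wt library 2 (adjusted p = 0.123). The C-type lectins had 7 of 139 higher and 3 lower, and 18 and 9 adjusted over the list alone (adjusted p = 0.00506, and adjusted p = 0.684 with an estimated correlation), lost without total wt library 1 (adjusted p = 0.0517), with a median of 0.25 that was 0.12 there and 0.13 without total glh1 library 2. The pan-neuronal markers had a median of 0.25 with 0 of 37 called and 0 adjusted over the list alone (adjusted p = 0.0155, and adjusted p = 0.848 with an estimated correlation), lost without total wt library 2 (median 0.21, adjusted p = 0.0560). The chromatin regulators had a median of -0.35 with 0 of 29 called and 0 adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.940 with an estimated correlation). Their call was lost without total glh1 library 1 (adjusted p = 0.0565), total wt library 2 (adjusted p = 0.200) or total wt library 3 (adjusted p = 0.104). The cytosolic ribosomal proteins had a median of 0.15 with 0 of 81 called and 0 adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.940 with an estimated correlation). Their call was lost without total glh1 library 2 (adjusted p = 0.134), total wt library 1 (adjusted p = 0.100) or total wt library 3 (adjusted p = 0.313). Their median was 0.30 without total wt library 2, and 0.25 and 0.25 without total glh1 libraries 1 and 3. The 7 male genes had a median of 0.46 with 0 called and 1 higher adjusted over the list alone (adjusted p = 0.0318, and adjusted p = 0.600 with an estimated correlation). Their call was lost without total glh1 library 1 (median 0.44, adjusted p = 0.0610) or total wt library 1 (median 0.52, adjusted p = 0.0517). The log2 fold change in total RNA ran with exon length at a Spearman correlation of -0.219 across 9890 genes. With that trend removed the vitellogenin (adjusted p = 0.0840), ribosomal protein (adjusted p = 0.428), chromatin (adjusted p = 0.151) and male lists (adjusted p = 0.0840) no longer passed. The genes gld-2 (adjusted p = 0.0538), nlp-47 (adjusted p = 0.101) and nlp-69 (adjusted p = 0.105) lost their calls as well.

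The lists of muscle markers (median -0.08, adjusted p = 0.592), translation factors (0.01, adjusted p = 0.975), heat shock (0.01, adjusted p = 0.758) and unfolded protein response genes (0.09, adjusted p = 0.600) did not pass in total RNA, nor did collagens (-0.20, adjusted p = 0.460), P granule genes (-0.17, adjusted p = 0.0628) and histones (-0.17, adjusted p = 0.686). Without wt culture 1 the collagens (-0.27, adjusted p = 0.00345), P granule genes (-0.18, adjusted p = 0.00406) and heat shock genes (0.38, adjusted p = 0.0174) passed, though not with an estimated correlation (adjusted p = 0.893, 0.229 and 0.392).

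Over all genes, 85 were higher and 71 lower in total RNA of the libraries labelled glh1, and 2945 had an unadjusted p under 0.05 where chance gives 826. All 3 libraries of a genotype lay above all 3 of the other for 33.7% of the genes, against 10% by chance. With upper-quartile scaling the split was 113 to 51, and the median of all genes moved from -0.07 to 0.08. The count changed with the libraries kept, and a group of 3 with 1 left out keeps 2, which weakens the test. Higher and lower genes numbered 166 and 270 without total wt library 1, 18 and 18 without library 2, and 14 and 17 without library 3. Without total glh1 libraries 1, 2 and 3 in turn they numbered 17 and 15, 15 and 15, and 20 and 16.

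**Figure D3:**
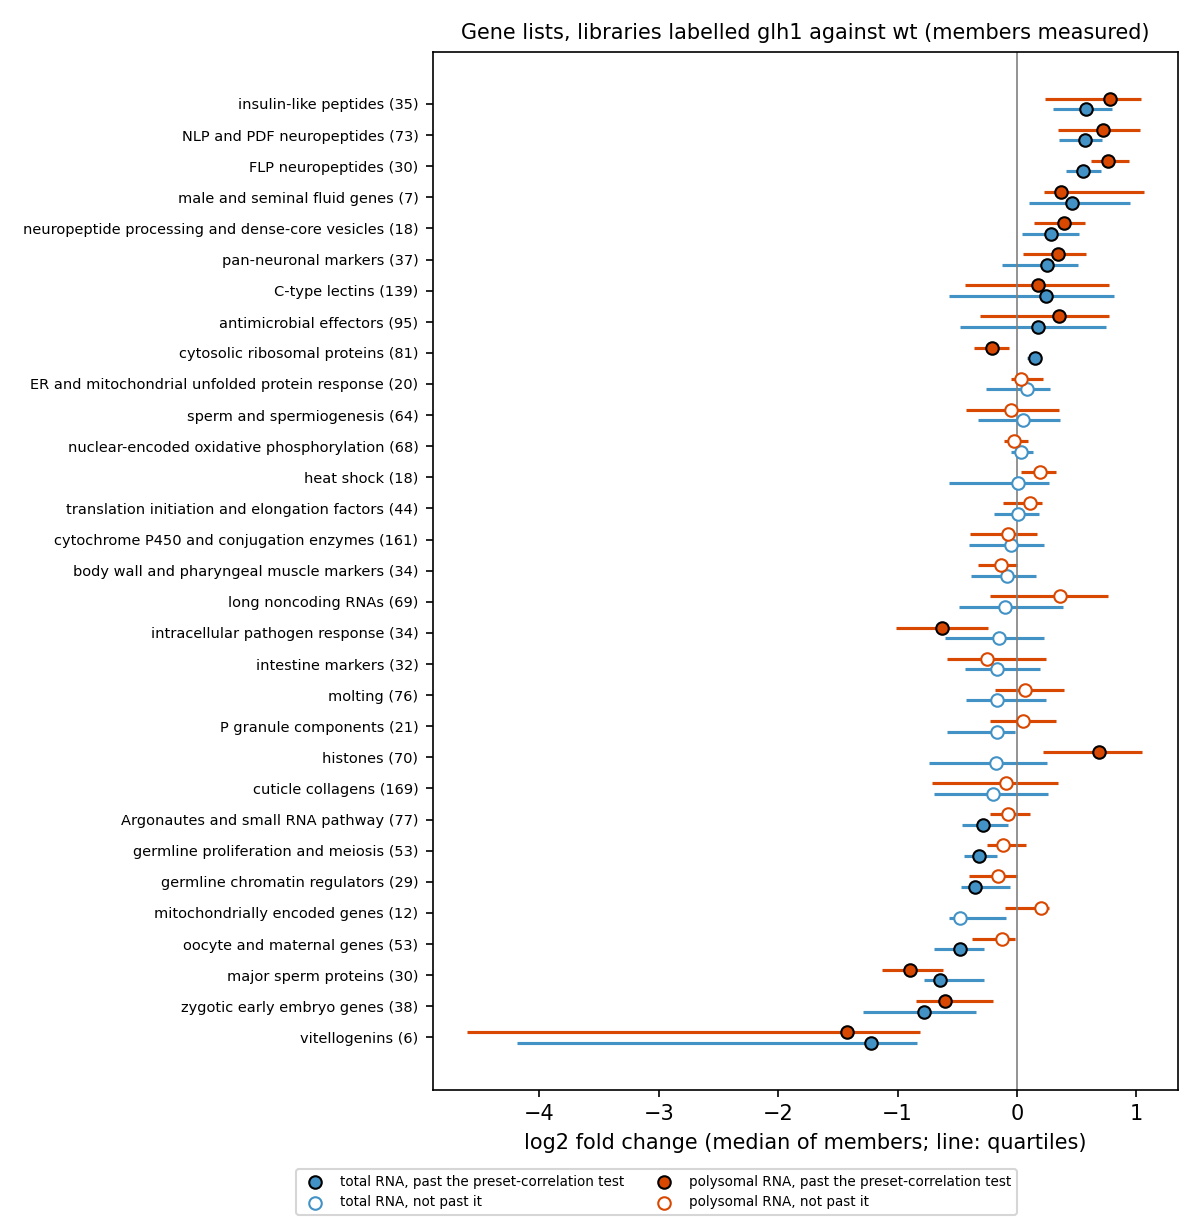
Median log2 fold change of each gene list in the libraries labelled glh1 against wt (points), with the quartiles of its members (lines), in total and polysomal RNA. Filled points passed the list test with a preset correlation, and none passed with an estimated correlation.

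The second comparison asks how the RNA in the polysome fraction differed between genotypes. In polysomal RNA of the libraries labelled glh1, thn-1 rose from 109 ± 14.6 to 716 ± 400 CPM (SD, n = 3), a log2 fold change of 2.72 ± 0.32 (SE; adjusted p = 0.00155). The genes tag-293 (4.12 ± 0.44, adjusted p = 8.65e-04), clx-1 (3.93 ± 0.40, adjusted p = 7.97e-04) and clec-130 (3.77 ± 0.54, adjusted p = 0.00604) rose as well. The genes fbxa-206 (-3.24 ± 0.34, adjusted p = 8.55e-04), ztf-28 (-2.98 ± 0.23, adjusted p = 8.70e-05), msrp-3 (-2.24 ± 0.32, adjusted p = 0.00610) and bath-7 (-1.88 ± 0.30, adjusted p = 0.0107) fell, as did the polo-like kinase gene plk-3 (-2.40 ± 0.39, adjusted p = 0.0129). These 9 genes kept their calls when any of the 6 polysomal libraries was left out, which cannot part strain background from genotype. Of those that fell, fbxa-206, msrp-3 and bath-7 lay within 50 kb of other genes lower in glh1. When only the polysomal libraries entered the fit, ztf-28 alone of the 9 kept its call, and tag-293, clx-1 and fbxa-206 (adjusted p = 0.0728 each), thn-1 and clec-130 (adjusted p = 0.144 each), msrp-3 (adjusted p = 0.178), plk-3 (adjusted p = 0.193) and bath-7 (adjusted p = 0.288) lost theirs. The other largest rises under the naming rule were those of col-50 (2.94), tsp-4 (2.71), fipr-24 (2.29), clec-158 (2.18), txt-12 (2.03), scl-14 (1.99), oac-31 (1.80) and clec-43 (1.78). The other largest falls under the naming rule were those of bath-1 (-2.59), col-80 (-2.30), haao-1 (-2.07), btb-4 (-1.94), nspd-9 (-1.89), msrp-4 (-1.83) and col-160 (-1.82). Each gene of these last 2 groups lost its call without at least 1 library. Y102A5C.2, which has no class name, fell further here too (-5.98, adjusted p = 2.72e-05, the smallest of this comparison).

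In polysomal RNA of the libraries labelled glh1 the neuropeptide lists had higher medians and the major sperm protein list a lower median at the preset correlation, and few of their genes were called. The FLP precursors had a median log2 fold change of 0.76 (adjusted p = 2.34e-16, and adjusted p = 0.460 with an estimated correlation), where 1 of 30, flp-17, rose (0.98 ± 0.21) and 25 were higher adjusted over the list alone. The NLP and PDF precursors had a median of 0.72 (adjusted p = 1.92e-16, and adjusted p = 0.460 with an estimated correlation). Of 73 measured, 4 rose, nlp-57 (1.60 ± 0.29), ntc-1 (1.72 ± 0.36), nlp-13 (0.95 ± 0.20) and nlp-69 (0.88 ± 0.19), and adjusted over the list alone 39 were higher and 1 lower. The insulin-like peptides had a median of 0.78 (adjusted p = 2.72e-07, and adjusted p = 0.547 with an estimated correlation), with 1 of 35 higher, ins-3 (1.55 ± 0.32), and 9 adjusted over the list alone. The calls of flp-17, nlp-57, ntc-1, nlp-13, nlp-69 and ins-3 were lost without wt library 3 (adjusted p from 0.118 to 0.217), and that of nlp-69 also with the length trend removed (adjusted p = 0.0765). The major sperm protein genes had a median of -0.90, with 0 of 30 called and 12 lower adjusted over the list alone (adjusted p = 2.63e-15, and adjusted p = 0.547 with an estimated correlation). Their summed level was 1425 and 1447 CPM in polysomal glh1 libraries 1 and 2, 4944 in library 3, and 3957 to 5190 in the wt libraries. Without glh1 library 3 their median was -1.77 and 28 of 30 fell, and the list passed with an estimated correlation as well (adjusted p = 0.0188). That test was chosen after the data were seen, and library 3 held the glh1 level nearest to wt, so the pass is no independent support. The same library raised the peptide lists, and without it the insulin-like median was 0.27 (adjusted p = 0.0366), the FLP median 0.49 (adjusted p = 3.57e-10) and the NLP and PDF median 0.49 (adjusted p = 4.65e-08). With an estimated correlation none of these 3 lists then passed, and the lowest adjusted p was 0.375.

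The zygotic embryo genes had a median of -0.60 in polysomal RNA, with 0 of 38 called and 0 adjusted over the list alone (adjusted p = 1.67e-04, and adjusted p = 0.547 with an estimated correlation). The histone genes had a median of 0.69, with 0 of 70 called, and 16 higher and 1 lower adjusted over the list alone (adjusted p = 1.16e-06, and adjusted p = 0.564 with an estimated correlation), and their median was 0.44 (adjusted p = 0.0345, and adjusted p = 0.821 with an estimated correlation) without glh1 library 3. The remaining 8 list calls in polysomal RNA were each lost without at least 1 library. The peptide processing genes (median 0.39, adjusted p = 0.00623, and adjusted p = 0.564 with an estimated correlation) lost theirs without glh1 library 1 (median 0.20, adjusted p = 0.0764), glh1 library 2 (median 0.25, adjusted p = 0.0893) or wt library 3 (median 0.27, adjusted p = 0.0858). The pan-neuronal markers (0.34, adjusted p = 0.00397, and adjusted p = 0.547 with an estimated correlation) lost theirs without wt library 3 (median 0.22, adjusted p = 0.0516). The vitellogenins (-1.42, adjusted p = 0.00700, and adjusted p = 0.564 with an estimated correlation) lost theirs without glh1 library 3 (adjusted p = 0.0592), wt library 2 (adjusted p = 0.0755) or wt library 3 (adjusted p = 0.100). The pals genes of the intracellular pathogen response (-0.63, adjusted p = 4.70e-04, and adjusted p = 0.564 with an estimated correlation), of which pals-9 fell (-2.18 ± 0.42), lost theirs without wt library 1 (median -0.26, adjusted p = 0.285). The antimicrobial effectors (0.35, adjusted p = 0.00397, and adjusted p = 0.792 with an estimated correlation) lost theirs without glh1 library 3 (median -0.15, adjusted p = 0.936), where the sign changed, or wt library 1 (median 0.21, adjusted p = 0.36), and without glh1 library 1 their median was 0.56. The C-type lectins (0.18, adjusted p = 0.00700, and adjusted p = 0.547 with an estimated correlation) lost theirs without glh1 library 3 (median 0.13, adjusted p = 0.111) or wt library 1 (median 0.10, adjusted p = 0.36). The ribosomal proteins (-0.20, adjusted p = 0.00562, and adjusted p = 0.892 with an estimated correlation) lost theirs without glh1 library 1 (median 0.01, adjusted p = 0.991) or 2 (median 0.02, adjusted p = 0.499), where the sign changed, or wt library 2 (adjusted p = 0.472) or 3 (adjusted p = 0.385). The male genes (0.37, adjusted p = 0.0344, and adjusted p = 0.460 with an estimated correlation) lost theirs without glh1 library 2 (adjusted p = 0.0502). Without glh1 library 3 the medians of the ribosomal proteins and male genes were -0.80 and 0.73, and without wt library 1 -0.53 and 0.68. Without wt library 3 the median was 0.60 for the male genes and 0.28 for the lectins. Adjusted over the list alone, 4, 0, 3, 1, 11, 23, 0 and 2 members of these 8 lists passed in the direction of the list, against 0, 0, 0, 1, 2, 7, 0 and 0 over all genes.

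Other lists passed in polysomal RNA after libraries were left out. Without wt culture 1 these were heat shock (1.04, adjusted p = 5.09e-05), collagens (-0.47, adjusted p = 1.79e-05), intestine markers (-0.63, adjusted p = 4.73e-04), oocyte (-0.37, adjusted p = 4.96e-06), germline (-0.20, adjusted p = 0.0338), chromatin (-0.30, adjusted p = 0.0204), respiratory chain (-0.21, adjusted p = 0.0483) and long noncoding RNA lists (0.47, adjusted p = 0.0338). None of these 8 passed with an estimated correlation (adjusted p from 0.170 to 0.940), while the vitellogenins (adjusted p = 0.0215) and zygotic genes (adjusted p = 0.0363) did. Both of the latter lists were lower in wt culture 1 than in the other wt cultures, so their passes are no independent support. The other lists that passed without glh1 library 3 were collagens (-0.59, adjusted p = 3.23e-12), sperm (-0.31, adjusted p = 1.08e-10), respiratory chain (-0.44, adjusted p = 4.59e-12), muscle (-0.16, adjusted p = 0.0324) and translation factor lists (-0.19, adjusted p = 0.0240), and none of these 5 passed with an estimated correlation (adjusted p from 0.375 to 0.811).

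Over all genes, 90 were higher and 85 lower in polysomal RNA of the libraries labelled glh1, and 2590 had an unadjusted p under 0.05 where chance gives 826. All 3 libraries of a genotype lay above all 3 of the other for 17.6% of the genes, against 10% by chance. Another split, of polysomal glh1 libraries 1 and 2 with wt library 1 against the other 3, called 1229 genes. The excess over chance can thus not be put down to genotype alone. The counts were 0 and 3 when only the polysomal libraries entered the fit. They were 47 and 31, 91 and 51, and 154 and 248 without glh1 libraries 1, 2 and 3 in turn. They were 16 and 40, and 18 and 30 without wt libraries 2 and 3, and 320 genes were called without wt library 1, 113 of them higher.

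Both fractions shared 45 genes that were higher and 38 that were lower in the libraries labelled glh1, where independent lists would share 0.463 and 0.365. Of 248 genes called in either fraction, 244 had the same sign in both. Across the 16526 genes the log2 fold changes correlated with Pearson's r = 0.673 and Spearman's rho = 0.639, and genes are not independent replicates. Both fractions come from the same cultures, which alone raises such values. In 20 simulations with no genotype effect that kept this sharing, r was 0.287 and the covariance 0.0436, against an observed covariance of 0.224. Signs were drawn for each gene on its own, so these are average levels. They leave out the spread that a difference of 1 culture shared by many genes would add. Whether the observed covariance lies beyond that spread cannot be told from them.

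The third comparison asks which mRNAs were more or less abundant in the polysome fraction than in total RNA of wt. Collagen, neuropeptide and sperm protein lists had higher medians in the polysome fraction, and germline regulator and mitochondrially encoded lists had lower medians. The collagens of the cuticle had a median log2 fold change of 1.39, with 78 of 169 higher and 1 lower, and 94 and 1 adjusted over the list alone (adjusted p = 1.02e-11, and adjusted p = 0.519 with an estimated correlation). The gene dod-3 rose from 143 ± 26.9 to 700 ± 77.4 CPM (SD, n = 3), a log2 fold change of 2.29 ± 0.32 (SE; adjusted p = 2.33e-04). The transcription elongation factor gene tcer-1 fell from 67.9 ± 19.6 to 3.67 ± 0.441 (-4.21 ± 0.30, adjusted p = 1.89e-05), and the DNA helicase gene rtel-1 from 34.2 ± 8.21 to 3.20 ± 1.20 (-3.41 ± 0.30, adjusted p = 2.74e-05). The other largest rises under the naming rule were those of fipr-24 (2.54), cnc-2 (2.42), col-108 (2.42), nspc-4 (2.29), cnc-7 (2.28) and clx-1 (2.25). The calls of cnc-2 and nspc-4 were lost without total wt library 3 (adjusted p = 0.0630 and 0.0684) and that of cnc-7 without polysomal wt library 3 (adjusted p = 0.0520). With the length trend removed nspc-4 (adjusted p = 0.101) and cnc-7 (adjusted p = 0.109) did not pass. The other largest falls under the naming rule were those of epg-5 (-3.62), pqn-20 (-3.31), rmh-2 (-3.25), apc-17 (-3.25), the noncoding linc-40 (-3.24) and sdc-3 (-3.19). The antisense RNA anr-1 had 0 counts in each wt total library and 1.00 ± 1.04 CPM in polysomal RNA. That mean was 12.9-fold above a floor of 3 counts per library, and with an SD larger than the mean this is no firm lower bound.

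The mitochondrially encoded genes had a median of -2.45, and 12 of 12 fell, 12 adjusted over the list alone (adjusted p = 3.86e-11, and adjusted p = 0.519 with an estimated correlation). Of the germline proliferation and meiosis genes, 38 of 53 fell and 1 rose, and 40 and 3 did adjusted over the list alone (median -1.09, adjusted p = 4.18e-14, and adjusted p = 0.519 with an estimated correlation). The Notch receptor gene glp-1 (-2.56 ± 0.23, adjusted p = 3.32e-05) and the cohesin genes him-1 (-2.18 ± 0.21, adjusted p = 3.64e-05) and rec-8 (-1.76 ± 0.17, adjusted p = 3.73e-05) were among those that fell. In the small RNA pathway 47 of 77 fell and 5 rose, and 49 and 6 did adjusted over the list alone (median -0.97, adjusted p = 3.86e-11, and adjusted p = 0.519 with an estimated correlation). Among chromatin regulators 18 of 29 fell and 0 rose, and 20 and 1 did adjusted over the list alone (median -0.95, adjusted p = 2.66e-08, and adjusted p = 0.519 with an estimated correlation). The histone methyltransferase gene mes-4 (-2.27 ± 0.20, adjusted p = 3.12e-05) was 1 of those that fell. Of the pals genes 14 of 34 fell and 1 rose, and 14 and 1 did adjusted over the list alone (median -0.92, adjusted p = 0.00146, and adjusted p = 0.519 with an estimated correlation).

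Secreted peptide lists had higher medians in the polysome fraction of wt, and short genes lay higher in general. The NLP and PDF precursors had 46 of 73 higher and 1 lower, and 49 and 1 adjusted over the list alone (0.95, adjusted p = 4.36e-09, and adjusted p = 0.519 with an estimated correlation). The FLP precursors had 18 of 30 higher, and 21 adjusted over the list alone (0.82, adjusted p = 6.46e-05, and adjusted p = 0.519 with an estimated correlation). The insulin-like peptides had 18 of 35 higher, and 18 adjusted over the list alone (1.01, adjusted p = 2.07e-04, and adjusted p = 0.519 with an estimated correlation). The log2 fold change ran with exon length at a Spearman correlation of -0.499 across 9890 genes. With the length trend removed the NLP and PDF (0.30, adjusted p = 0.0920), FLP (0.17, adjusted p = 0.402) and insulin-like lists (0.26, adjusted p = 0.311) no longer passed. The major sperm protein genes had 28 of 30 higher, and 29 adjusted over the list alone (median 1.56, adjusted p = 8.70e-09, and adjusted p = 0.519 with an estimated correlation), and their median with the length trend removed was 0.62 (adjusted p = 3.93e-05, and adjusted p = 0.627 with an estimated correlation). The other sperm genes had 32 of 64 higher and 7 lower, and 32 and 7 adjusted over the list alone (0.78, adjusted p = 6.58e-04, and adjusted p = 0.552 with an estimated correlation). The antimicrobial effectors had 37 of 95 higher and 1 lower, and 37 and 1 adjusted over the list alone (1.10, adjusted p = 8.08e-07, and adjusted p = 0.519 with an estimated correlation). The molting genes had 29 of 76 higher and 3 lower, and 29 and 3 adjusted over the list alone (0.64, adjusted p = 5.36e-04, and adjusted p = 0.519 with an estimated correlation).

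The nuclear-encoded respiratory chain genes had 40 of 68 higher and 2 lower, and 44 and 2 adjusted over the list alone (0.85, adjusted p = 9.19e-08, and adjusted p = 0.592 with an estimated correlation). The intestine markers had 9 of 32 higher, and 8 adjusted over the list alone, and ftn-1 (1.63 ± 0.16) was among them (0.84, adjusted p = 0.00158, and adjusted p = 0.519 with an estimated correlation). The P granule genes had 11 of 21 lower, and 11 adjusted over the list alone (-0.67, adjusted p = 6.58e-04, and adjusted p = 0.519 with an estimated correlation). The oocyte genes had 23 of 53 lower and 4 higher, and 23 and 4 adjusted over the list alone (-0.55, adjusted p = 5.62e-04, and adjusted p = 0.683 with an estimated correlation). Neither passed with the length trend removed (adjusted p = 0.325 and 0.0874), and without polysomal wt library 1 their medians were -0.44 and -0.27. With the trend removed the ribosomal proteins (0.23 before, -0.45 after, adjusted p = 7.71e-06) and histones (0.38 before, -0.49 after, adjusted p = 0.00247), which did not pass before, passed with lower medians, though not with an estimated correlation (adjusted p = 0.748 and 0.738). The C-type lectins (0.44, adjusted p = 0.0226, and adjusted p = 0.519 with an estimated correlation) lost their call without polysomal wt library 3 (adjusted p = 0.0906). It was also lost with upper-quartile scaling (median 0.71, adjusted p = 0.0532). The long noncoding RNAs (-0.45, adjusted p = 0.0376, and adjusted p = 0.519 with an estimated correlation) lost theirs without total wt library 1 (adjusted p = 0.182), and without polysomal wt library 3 their median was -0.72. Adjusted over the list alone, 14 lectins were higher and 16 noncoding RNAs lower, against 25 and 17 over all genes. The vitellogenins (-0.57, adjusted p = 0.272) did not pass without a block and passed with the culture as a block (adjusted p = 0.0225). That pass is at the preset correlation, and an estimated correlation was not tried with the block.

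Over all genes of wt, 3321 were higher and 3272 lower in the polysome fraction, and the groups did not overlap for 49.2% of the genes, against 10% by chance. With upper-quartile scaling the split was 4833 to 2384, and the median of all genes moved from 0.06 to 0.32, so directions are relative to the scaling. Without total wt library 3 the number of higher genes was 1974.

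The fourth comparison asks the same of the libraries labelled glh1, where most of the same gene groups lay on the same sides. Mitochondrially encoded genes (12 of 12 lower, median -1.88, adjusted p = 7.31e-09, and adjusted p = 0.624 with an estimated correlation) were lower. So were germline genes (34 of 53 lower, 3 higher, -0.93, adjusted p = 2.12e-10, and adjusted p = 0.624 with an estimated correlation) and the small RNA pathway (43 of 77 lower, 9 higher, -0.78, adjusted p = 5.51e-08, and adjusted p = 0.624 with an estimated correlation). Chromatin regulators (18 of 29 lower, 1 higher, -1.06, adjusted p = 1.30e-07, and adjusted p = 0.624 with an estimated correlation) and pals genes (18 of 34 lower, -1.34, adjusted p = 2.76e-06, and adjusted p = 0.624 with an estimated correlation) were lower too. Adjusted over the list alone, 12, 34, 45, 20 and 20 were lower. Collagens (93 of 169 higher, 1 lower, 1.47, adjusted p = 3.75e-10, and adjusted p = 0.735 with an estimated correlation), molting genes (36 of 76 higher, 3 lower, 0.82, adjusted p = 1.18e-05, and adjusted p = 0.624 with an estimated correlation) and antimicrobial effectors (45 of 95 higher, 1 lower, 1.23, adjusted p = 1.52e-06, and adjusted p = 0.624 with an estimated correlation) were higher. So were NLP and PDF precursors (51 of 73 higher, 1 lower, 1.06, adjusted p = 3.75e-10, and adjusted p = 0.624 with an estimated correlation), FLP precursors (20 of 30 higher, 0.94, adjusted p = 2.72e-06, and adjusted p = 0.624 with an estimated correlation) and insulin-like peptides (18 of 35 higher, 1.34, adjusted p = 2.72e-05, and adjusted p = 0.624 with an estimated correlation). Adjusted over the list alone, 106, 40, 45, 55, 21 and 20 were higher. Histone genes had 27 of 70 higher, and 25 adjusted over the list alone (1.05, adjusted p = 3.50e-05, and adjusted p = 0.748 with an estimated correlation). The major sperm protein genes had 21 of 30 higher, and 22 adjusted over the list alone (1.23, adjusted p = 3.04e-04, and adjusted p = 0.794 with an estimated correlation). With the length trend removed the major sperm protein (adjusted p = 0.430), histone (adjusted p = 0.479) and insulin-like lists (adjusted p = 0.0556) no longer passed, and the FLP (adjusted p = 0.0409) and NLP and PDF lists (adjusted p = 0.00634) did, though not with an estimated correlation (adjusted p = 0.854 and 0.561). Without polysomal glh1 library 3 the medians were 0.41 for the major sperm proteins, 0.86 for the insulin-like peptides, 0.91 for the collagens and 0.78 for the antimicrobial effectors.

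Among genes with a class name, the largest rise in the libraries labelled glh1 was that of clx-1, from 9.05 ± 0.233 to 54.5 ± 33.5 CPM (SD, n = 3; 2.59 ± 0.37, adjusted p = 3.22e-04). It was followed by ins-29 (2.42), col-40 (2.40), fipr-10 (2.40), col-105 (2.32), col-174 (2.31), col-170 (2.30) and col-180 (2.26). The calls of fipr-10 and col-105 were lost without total glh1 library 3 (adjusted p = 0.0611 and 0.0501). The gene tcer-1 fell from 50.3 ± 5.03 to 4.04 ± 1.40 (-3.63 ± 0.29, adjusted p = 5.18e-05) and rtel-1 from 27.2 ± 2.36 to 3.46 ± 0.455 (-2.97 ± 0.29, adjusted p = 6.81e-05). The RNA component of RNase P, rpr-1 (-3.66), fell too, as did math-3 (-3.28), fbxa-163 (-3.25), snpc-1.1 (-2.95), rabx-5 (-2.94) and eri-12 (-2.91). The glh-1 mRNA was higher in the polysome fraction of these libraries (0.98 ± 0.26, adjusted p = 0.00885), a call lost without total glh1 library 1 (adjusted p = 0.0631) or 3 (adjusted p = 0.0622). In wt the log2 fold change of glh-1 was 0.04 ± 0.25 (adjusted p = 0.916). The glh-3 mRNA fell in wt (-0.70 ± 0.18, adjusted p = 0.00794) and in the libraries labelled glh1 (-0.71 ± 0.18, adjusted p = 0.00686). With the length trend removed the changes of glh-3 were -0.18 (adjusted p = 0.506) and -0.28 (adjusted p = 0.270), and both calls were lost.

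The respiratory chain genes (36 of 68 higher, 2 lower, 0.81, adjusted p = 1.18e-05, and adjusted p = 0.794 with an estimated correlation) and intestine markers (12 of 32 higher, 1 lower, 0.72, adjusted p = 0.00932, and adjusted p = 0.715 with an estimated correlation) had higher medians in the polysome fraction of the libraries labelled glh1, with 40 and 12 higher adjusted over the list alone. The P granule genes (8 of 21 lower, 8 adjusted over the list alone, -0.37, adjusted p = 0.0426, and adjusted p = 0.794 with an estimated correlation) lost their call without polysomal glh1 library 1 (adjusted p = 0.0600) or 2 (adjusted p = 0.0865), and with the length trend removed (median 0.09, adjusted p = 0.908). Upper-quartile scaling ended that call as well (median -0.21, adjusted p = 0.0583). Without polysomal glh1 library 3 the respiratory chain median was 0.33. The C-type lectins (31 of 139 higher, 27 adjusted over the list alone, 0.49, adjusted p = 0.0343, and adjusted p = 0.624 with an estimated correlation) lost theirs without library 3 (adjusted p = 0.0785). The vitellogenin (-0.89, adjusted p = 0.175), oocyte (-0.25, adjusted p = 0.131) and ribosomal protein lists (-0.12, adjusted p = 0.137) did not pass without a block and passed with the culture as a block (adjusted p = 0.0132, 0.0496 and 0.0445). These passes too are at the preset correlation only. The sperm genes other than major sperm proteins, which passed in wt, did not pass here (0.75, adjusted p = 0.0701), and whether the 2 genotypes differ in them is tested by the interaction below.

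Over all genes of the libraries labelled glh1, 3901 were higher and 3163 lower in the polysome fraction, and the groups did not overlap for 63.6% of the genes, against 10% by chance. Without total glh1 libraries 1 and 3 in turn, 2212 and 2096 were higher. With upper-quartile scaling the split was 4808 to 2624, and the median of all genes moved from 0.13 to 0.28. The log2 fold change ran with exon length at a Spearman correlation of -0.419 across 9890 genes. Both genotypes shared 2827 higher and 2591 lower genes, where independent lists would share 784 and 626, and 0 genes were called in opposite directions.

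**Figure D4:**
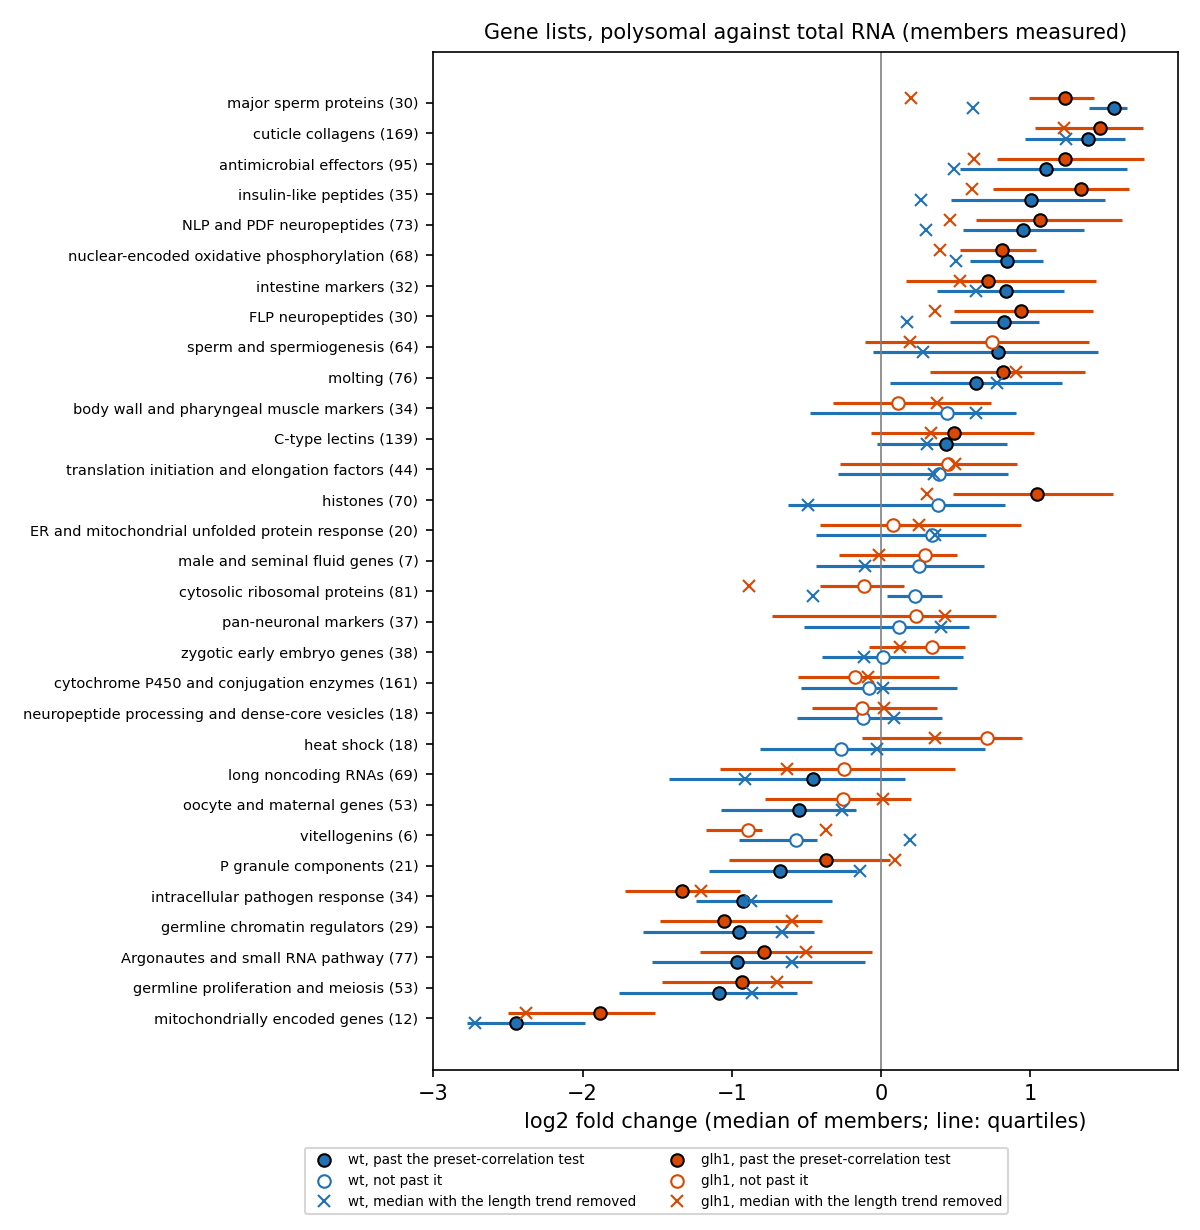
Median log2 fold change of each gene list in polysomal against total RNA for wt and for the libraries labelled glh1 (points), with the quartiles of its members (lines). Crosses show the median with the length trend removed, which lies nearer to 0 for the neuropeptide and insulin-like lists.

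**Figure D5:**
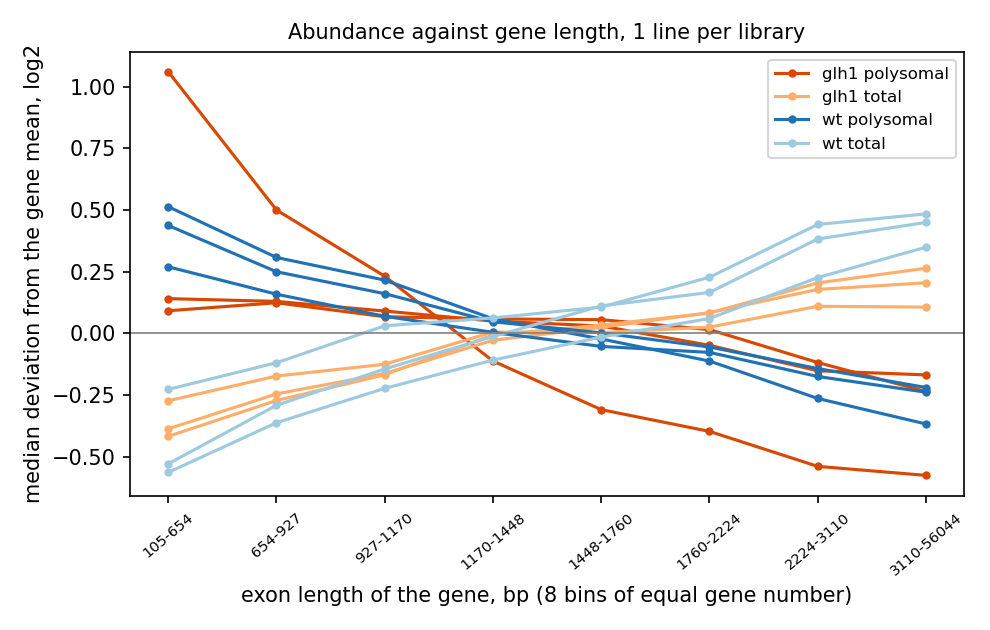
Median deviation of log2 abundance from each gene's mean in 8 bins of exon length, with 1 line per library. Polysomal libraries lie higher for short genes and total RNA libraries for long genes.

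The last comparison asks whether the polysome fraction changed differently in the 2 genotypes, as the difference of both log2 fold changes. The targeted gene glh-1 had a difference of 0.94 ± 0.36 (SE; adjusted p = 1). The germline regulators gld-2 (1.03 ± 0.24, adjusted p = 1) and lin-41 (1.06 ± 0.29, adjusted p = 1) had values of similar size. Both were called lower in total RNA of glh1, which enters the difference with a minus sign. Their positive values thus restate that fall in part and are no separate finding. The edgeR test called 0 genes higher and 0 lower, with 491 genes at an unadjusted p under 0.05 where chance gives 826. With the culture as a block, which follows the pairing, it called 0 genes too, with 538 under 0.05. Since small p-values were fewer than chance gives, 0 calls are no evidence that the genotypes did not differ. With 1 library left out, the number of genes under 0.05 ran from 277 without total glh1 library 3 to 1563 without polysomal glh1 library 3. In both of these fits 0 genes were called. DESeq2 called 1 higher and 2 lower, and limma on the deposited log2 values called 0 and 0. Without polysomal glh1 library 1, edgeR called 0 higher and 1 lower. The groups did not overlap for 10.9% of the genes, against 10% by chance. Of the gene lists, 12 passed with the preset correlation. The histone genes (median difference 0.67, adjusted p = 1.28e-11, and adjusted p = 0.941 with an estimated correlation) and the cytosolic ribosomal proteins (-0.35, adjusted p = 3.95e-11, and adjusted p = 0.941 with an estimated correlation) kept that call when any 1 of the 12 libraries was left out, but the sizes depended on single libraries. The histone median was 0.28 without polysomal glh1 library 3. The ribosomal protein median was -0.18, -0.12 and -0.94 without polysomal glh1 libraries 1, 2 and 3, and -0.75 and -0.17 without polysomal wt libraries 1 and 3. The other 10 calls were each lost without at least 1 library.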

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

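The gene lists and their test were chosen before the result was seen, and leaving out wt culture 1 was chosen after it. In 12 lists the polysomal to total ratio differed between genotypes by the test of the interaction with a preset correlation, and positive values mean a higher ratio in the libraries labelled glh1. Histones (median log2 difference 0.67, adjusted p = 1.28e-11), mitochondrially encoded genes (0.56, adjusted p = 0.0349), oocyte genes (0.31, adjusted p = 7.07e-06), P granule genes (0.27, adjusted p = 0.00252), germline genes (0.22, adjusted p = 0.0131), the small RNA pathway (0.17, adjusted p = 0.0131) and molting genes (0.16, adjusted p = 0.0492) were higher. The pals genes (-0.40, adjusted p = 2.86e-05), ribosomal proteins (-0.35, adjusted p = 3.95e-11), major sperm proteins (-0.28, adjusted p = 1e-06), other sperm genes (-0.14, adjusted p = 8.65e-04) and P450 and conjugation enzymes (-0.043, adjusted p = 0.0349) were lower. With an estimated correlation the adjusted p was 0.974 for the germline list and 0.941 for each of the other 11, and no single member of any list was called.

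Of the 12 calls, 10 were lost without at least 1 library. Without polysomal wt library 1 the oocyte (adjusted p = 0.723), P granule (adjusted p = 0.662), small RNA (adjusted p = 0.662), germline (adjusted p = 0.319), pals (adjusted p = 0.318), P450 (adjusted p = 0.723), molting (adjusted p = 0.229), mitochondrially encoded (adjusted p = 0.308) and sperm lists (adjusted p = 0.0783) no longer passed. There the oocyte (-0.04), P granule (-0.07) and small RNA medians (-0.03) changed sign. The major sperm proteins no longer passed without polysomal glh1 library 1 (adjusted p = 0.116) or 2 (median 0.01, adjusted p = 0.0557), and without library 3 their median was -1.18. Without wt culture 1 the mitochondrially encoded median was -0.15 (adjusted p = 0.514). Total wt library 2 ended the oocyte (adjusted p = 0.0799) and P granule calls (adjusted p = 0.177) when left out, among others. Total glh1 library 1 ended those of the germline (adjusted p = 0.164) and small RNA lists (adjusted p = 0.132), total glh1 library 3 that of the mitochondrially encoded genes (adjusted p = 0.125), polysomal glh1 library 3 that of the molting genes (adjusted p = 0.966), total wt library 1 that of the mitochondrially encoded genes (adjusted p = 0.926) and total wt library 3 that of the germline list (adjusted p = 0.516). Only the histone and ribosomal protein calls were kept in each of the 12 tests with 1 library left out, but their sizes moved. The histone median was 0.28 without polysomal glh1 library 3, and the ribosomal protein median ran from -0.12 without polysomal glh1 library 2 to -0.94 without library 3. Without total wt library 1 the oocyte, P granule, germline and small RNA medians were larger (0.51, 0.47, 0.39 and 0.31), and the sperm median was -0.49 without polysomal glh1 library 3. No explanation was tested for these differences.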

How the results depend on the processing

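The tests without wt culture 1, without annotated rRNA genes and with the length offset, and the splits of the libraries, were chosen after the results were seen. No named gene that was called reversed under any alternative, and the counts have no direction. Medians of called lists did change sign. In polysomal RNA the antimicrobial effectors went from 0.35 to -0.15 without polysomal glh1 library 3, and the ribosomal proteins from -0.20 to 0.01 and 0.02 without glh1 libraries 1 and 2. In glh1 the P granule genes went from -0.37 to 0.09 with the length offset. For the interaction the oocyte, P granule, small RNA, major sperm protein, sperm, P450, molting and mitochondrially encoded medians did so too. In total RNA the counts of higher and lower genes were 711 and 626 with only the groups compared, 417 and 464 by DESeq2, 905 and 658 without wt culture 1, and 131 were higher without rRNA genes. DESeq2 shared 154 of the 156 called genes in the same direction, and only the groups compared and leaving out wt culture 1 shared 156. With each library left out they ran from 14 to 166 and from 15 to 270, and list calls from 14 to 16.

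In polysomal RNA they were 46 and 42 with the strict filter, 0 and 3 with only the groups compared in edgeR (1487 at an unadjusted p under 0.05), 458 and 307 by DESeq2, 682 and 774 without wt culture 1, and 179 and 162 with the length offset. With each library left out they ran from 16 to 154 and from 30 to 248, and list calls from 12 to 20.

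In the fraction comparisons 2067 genes of wt and 2546 of the libraries labelled glh1 were at least 2-fold higher. With the culture as a block, which follows the pairing, 3963 genes were higher and 3461 lower in wt. In glh1 4363 were higher and 3543 lower, and the interaction had 0 called genes with that block. With each library left out, higher genes ran from 1974 to 3444 in wt and from 2096 to 3880 in glh1, lower genes from 2427 to 3165 and from 2487 to 3300, and list calls from 18 to 21 and from 17 to 18. For the interaction DESeq2 called 1 gene higher and 2 lower, and with each library left out edgeR called 0 higher, 0 to 1 lower and 9 to 18 lists. The correlation of the genotype effects ran from 0.597 to 0.656 with each library left out. With an estimated correlation and all libraries 0 lists were called in any of the 5 comparisons, and with the length offset 0 as well. Without wt culture 1 it called 3 in total RNA, 2 in polysomal RNA and 0 in the others, and without polysomal glh1 library 3 it called 1 in polysomal RNA and 0 in the others. Both were chosen after the results were seen. Apart from the smaller number of libraries where some were left out, the cause was not tested.

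Of the called genes named in the text, 8 of 32 in total RNA, 9 of 32 in polysomal RNA, 19 of 22 in wt and 15 of 18 in glh1 kept their calls with any library left out. With the number as a block, whose deviations correlated at 0.0877 to 0.117 in total and 0.0518 to 0.306 in polysomal RNA, 71 and 65 genes were called in total and 90 and 93 in polysomal RNA. A group of 3 with 1 library left out keeps 2, and the self-test called 19 of 100 genes with a 2-fold change, so smaller changes are mostly missed.

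The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split called 156 genes in total RNA and the highest other 0 (1 of 10 as large), with 6593 and 0 in wt (1), 7064 and 0 in glh1 (1) and 0 and 0 for the interaction (10). In polysomal RNA the real split called 175 and another 1229 (2 of 10 as large). That split set polysomal glh1 libraries 1 and 2 with wt library 1 against the other 3, which points to a structure of the samples other than genotype.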

Other observations

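All tests of explanations in this part except that of counts that are not whole in the clusters were chosen after the result was seen. The yolk protein gene vit-3 was at 0.685 CPM in total RNA and 0.274 in polysomal RNA of wt culture 1, at 111 and 71.4 in wt culture 2, and at 93.7 and 75.1 in wt culture 3. In the libraries labelled glh1 it was at 0.306 to 1.13, and its log2 fold change between genotypes did not pass in total RNA (-6.21 ± 1.69, adjusted p = 0.0975). It passed by DESeq2 (adjusted p = 0.00281), without total wt library 1 (adjusted p = 0.0346) and without wt culture 1 (adjusted p = 8.35e-05), and the adjusted p under the other alternatives ran from 0.0555 to 0.369. The gene was chosen after its values were seen.

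Wt culture 1 lay with the glh1 cultures on the second component. With markers taken without this culture, 51 of 138 lay nearer to wt than to glh1 (37%) and 87 nearer to glh1. In the glh1 cultures 0 of 16, 0 of 19 and 0 of 32 lay nearer to wt, and in wt cultures 2 and 3 15 of 15 and 8 of 8. Each culture had its own markers, so these shares are not of the same genes. The 51 argue against a mislabelled culture, though wt culture 1 did not behave like the other wt cultures either. In rRNA share its total RNA library differed from that of wt culture 2 by 1.32 percentage points, against a span of 14.4 among the total glh1 libraries, but lay 83.06 from it on the component, where those spanned 2.64, and in polysomal RNA these values were 2.46, 42.6, 86.8 and 8.62, which argues against the rRNA share. The vitellogenin, oocyte and zygotic lists were lower in it than in both other wt cultures in 6 of 6 comparisons. Both fractions of a culture come from 1 lysate, so these are not 6 separate observations. Another developmental stage at harvest may explain its place, and this stays open because harvest times per culture are not given. If so, the genotype contrasts would hold stage as well as genotype, since wt cultures 2 and 3 alone carry the high yolk and oocyte values.

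Neuropeptide and insulin-like lists were higher in polysomal RNA, and germline, small RNA, chromatin and mitochondrially encoded lists lower. With the trend on exon length removed, 0 of 3 peptide lists passed in wt (NLP and PDF median 0.95 before and 0.30 after) and 2 of 3 in glh1 (1.06 and 0.46), so gene length, by a technical or a biological route, may account for much of both. In glh1 the NLP and PDF (adjusted p = 0.00634) and FLP lists (adjusted p = 0.0409) still passed, at the preset correlation only, which argues against length as their whole cause there as far as that correlation holds. The NLP and PDF list did not pass the interaction (adjusted p = 0.355) and passed at the preset correlation with the trend removed (0.20, adjusted p = 0.00465), while with the trend kept and polysomal glh1 library 3 left out the median was -0.09 (adjusted p = 0.0161), and neither passed with an estimated correlation (adjusted p = 0.799 and 0.746). Of the 8 tests of the lower lists, 8 passed at the preset correlation and 0 with an estimated correlation (adjusted p from 0.304 to 0.611), with germline medians of -0.86 in wt and -0.70 in glh1, which argues against gene length as their whole cause as far as the preset correlation holds.

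Genes lower in the libraries labelled glh1 lay in clusters. Of 118 genes lower in either fraction, 31 lay within 50 kb of another, against a median of 14 in 10000 random sets of tested genes (permutation test, p = 0.0005). That argues against placement of single genes at random. The random sets did not keep neighbouring family members together, such as the bath, msrp and clec genes, so the test cannot tell how much such families add. The 130 higher genes clustered too (32 against 16, permutation test, p = 0.003), so this is not special to lower genes. Of the 31, 25 had more than 3 counts in each glh1 library, a floor that a few reads shared between paralogs could pass. In their lowest glh1 library F52C6.3 (4), bath-7 (5), F52C6.4, bath-19 and Y54G2A.50 (6 each) and WBGene00018669 (6.007) lay just above it. A deletion of whole blocks stays open for these and for the other 6. It is argued against for genes with far more and whole counts, such as bath-2 (204), fbxc-45 (114) and F08H9.2 (284). Reads divided between paralogs leave counts that are not whole (to within 0.000001). Of the 31 genes, 9 had such counts, a share between the bounds set beforehand for either answer, so the planned test does not decide. For the 22 with whole counts in each library, a split made after the result was seen, divided reads are argued against. They stay open for the other 9. Strain background (3 lower genes within 1 Mb of glh-1) cannot be told apart from genotype, since each genotype is given as 1 strain.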
